A study of Rattus with 6 samples.

How the data were processed

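RNA was sequenced from 6 libraries of rat cardiac fibroblasts, 3 titled siCtrl and 3 transfected by lipofection with an siRNA against Nono. The labels name 48 h as the harvest time for RT-qPCR and western blotting and give no separate time for sequencing. Per the labels' protocols, DNase-treated total RNA went through poly(A) selection and a stranded mRNA library kit. Per the submitters' processing notes, HISAT2 and edgeR were used with genome build mRatBN7.2; their versions, the counting tool and its use of strand are not given in the sources used here. Antisense and overlapping genes, and near-identical copies such as histone and RT1 genes, are therefore uncertain. The files give each gene's symbol and chromosome but no positions, so none are printed.

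The deposited count table, whose raw read counts per gene are whole numbers per the values, held 21378 genes. The deposited FPKM table held 21081 of these genes, with values that the authors scaled by gene length and library size. The count table was the basis of the main results and the FPKM table was used for alternatives and for gene lengths, which were recovered as count / FPKM / library total where FPKM was at least 0.1 (98.2% of tested genes had one). There were 0 columns of other samples in either table. Total counts ranged from 27792357 to 33365588 per library, so that 3 counts, the limit that a count of 0 allows, correspond to 0.0899 to 0.108 CPM; this limit covers counting error only. Samples were grouped by their titles. Each library was counted as a separate sample, as its title gives it. Libraries of a group were not copies of 1 set of counts (chi-square per degree of freedom from 3.18 to 7.58 over genes with at least 10 counts), which does not tell separate cultures from repeated preparations.

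Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were filtered with filterByExpr, which left 14412, and libraries were scaled by TMM. The quasi-likelihood test (estimateDisp, glmQLFit, glmQLFTest) compared siNONO with siCtrl, two-sided, with 4 residual degrees of freedom, a common biological coefficient of variation of 4.82% and Benjamini-Hochberg adjustment over all genes tested at a threshold of 0.05. SE was the log2 fold change divided by the square root of the F statistic. CPM values are TMM-scaled, with the SD over 3 libraries. Single values were compared with an exact two-sided permutation test.

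The design, the 24 pathway lists, the 7 marker lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule named Nono and its paralogs Sfpq and Pspc1. It named the 10 largest rises and 10 largest falls among genes past the threshold with mean CPM of at least 5, a proper symbol and no overlap between groups, and from each list up to 2 members past the threshold with the largest rise and up to 2 with the largest fall, or the member with the lowest p where none passed. Genes named beyond it are said to lie outside it or to have been chosen after their values were seen. The 13 mitochondrial genes were matched through the names used in the files (ND1 for Mt-nd1, for example). Lists with at least 5 tested members were tested with camera (preset correlation 0.01, Benjamini-Hochberg over the 31 lists), with a correlation estimated per list and with fry. A further 9 lists were composed after the data were seen and were adjusted over those 9 alone.

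Alternatives were DESeq2 size factors, total library size and upper-quartile factors; no filter and a filter of CPM of at least 1 in 3 libraries; the DESeq2 1.42.0 Wald test, the edgeR exact test, limma-voom and robust quasi-likelihood fits; a replicate block; a gene length correction with and without the block; limma-trend on log2(FPKM + 1), on log2(FPKM + 0.1) and on genes with at least 1 FPKM in 3 libraries; a threshold of 0.01; and leaving out each library. The fits were tested on simulated data. In 10 draws of counts for the 14412 genes from the means, library sizes and dispersions of siNONO against siCtrl, with 200 genes changed, the edgeR test recovered 37% of the 1.2-fold, 75% of the 1.5-fold, 92% of the 2-fold and 99.8% of the 4-fold changes, and 7.49% of its calls were false, above the nominal 5%. The limits for passing this test were loosened after a first single draw had failed them. With 1 list of 46 genes shifted, camera called that list and 0 of the 30 others. The simulated genes were drawn independently, so this does not cover lists whose members vary together. In the data the correlation estimated per list reached 0.91, for ribosomal protein genes. A length trend added to the simulated counts (Spearman rho 0.693) shrank to 0.0169 with the length correction. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.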

Results

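Gene expression was measured by poly(A)-selected RNA sequencing in cultured rat cardiac fibroblasts, the matrix-producing cells of the heart, bought from a commercial supplier. The cells were titled siCtrl (3 libraries) or siNONO, transfected with an siRNA against Nono (3 libraries). NONO is a nuclear RNA- and DNA-binding protein of the DBHS family, found in paraspeckles and known for roles in splicing, transcription and DNA repair. The series asks how the transcriptome of these cells differs with and without NONO. Its title also speaks of splicing, which gene-level values cannot address and which was not analysed here. Total counts per library were 27792357, 28597437 and 32869992 in siCtrl replicates 1, 2 and 3, and 29692746, 33022889 and 33365588 in siNONO replicates 1, 2 and 3. Of 21378 genes with counts, 14412 were tested. Adjusted p-values below are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and log2 fold changes are siNONO minus siCtrl with their standard error (SE). The labels do not say whether the replicates came from separate cultures, so these p-values measure only the spread between these samples, which may be technical. The labels describe the control libraries both as siCtrl and as cells given an empty vector, so what the controls received is not settled here.

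Nono (gene-Nono, chromosome X) was lower in every siNONO library. Its level was 237, 233 and 247 CPM (counts scaled to library size and TMM factor) in siCtrl replicates 1, 2 and 3 and 69.9, 76.1 and 73.6 CPM in siNONO replicates 1, 2 and 3. The means were 239 ± 7.15 and 73.2 ± 3.15 CPM (SD, n = 3 each; exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give). The siNONO libraries thus held 30.7% of the control level, a log2 fold change of -1.70 ± 0.05 (SE; edgeR adjusted p = 4.57e-11). Both paralogs of Nono in the DBHS family, which form dimers with it, rose. Sfpq (gene-Sfpq, chromosome 5) went from 174 ± 7.79 to 224 ± 6.91 CPM, a log2 fold change of 0.36 ± 0.04 (edgeR adjusted p = 3.45e-05). Pspc1 (gene-Pspc1, chromosome 15) went from 18.3 ± 2.04 to 33.7 ± 0.794 CPM, a log2 fold change of 0.88 ± 0.07 (edgeR adjusted p = 6.35e-07).

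**Figure D1:**
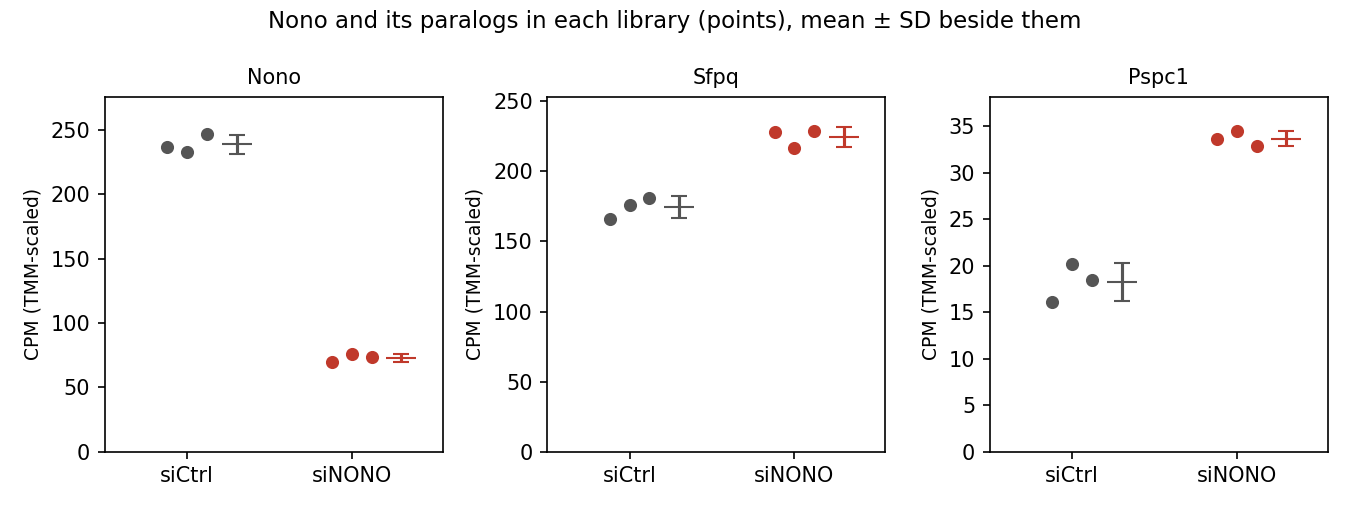
CPM (TMM-scaled, linear axis from 0) of Nono, Sfpq and Pspc1 in the 3 siCtrl and 3 siNONO libraries; points are libraries, and the bar beside them is the mean ± SD. Nono lay between 233 and 247 CPM in siCtrl and between 69.9 and 76.1 CPM in siNONO, while Sfpq and Pspc1 lay higher in each siNONO library than in any siCtrl library.

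Knockdown went with a broad but mostly small change of the transcriptome, with higher levels of nearly all tested interferon-induced genes and a fall of the opioid peptide precursor Penk. Of the 14412 genes tested, 4630 (32.1%) changed by edgeR's quasi-likelihood test at an adjusted p threshold of 0.05, 2338 raised and 2292 lowered. The median absolute log2 fold change of these genes was 0.30, and 266 changed at least 2-fold, 133 in each direction. The siCtrl and siNONO values did not overlap for 6481 genes (45.0% of those tested), where chance gives 10%. With scaling by total library size alone the split was 3174 raised to 1673 lowered (65.5% raised, against 50.5% above), and with log2(FPKM + 1) it was 2829 to 1546. The median log2 fold change of all tested genes was then 0.05 and 0.03, against 0.00 above.

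Among genes with a symbol, a mean of at least 5 CPM and no overlap between groups, the largest rises were those of Smpd3, Rsad2, Ifit3, Cmpk2, Cfb, Cxcl11, Aim2, Mx2, Gbp1 and Cgnl1. Smpd3 (chromosome 19), which encodes neutral sphingomyelinase 2, rose from 3.62 ± 0.243 to 21.1 ± 1.84 CPM (SD, n = 3 each), a log2 fold change of 2.54 ± 0.10 (edgeR adjusted p = 8.60e-10). Cfb (chromosome 20), complement factor B, rose from 273 ± 59.1 to 884 ± 85.6 CPM, a log2 fold change of 1.70 ± 0.11. Aim2, a sensor of cytosolic DNA, rose by 1.60 ± 0.17, the guanylate-binding protein gene Gbp1 by 1.47 ± 0.19 and Cgnl1, a junction protein related to cingulin, by 1.46 ± 0.09 on the log2 scale. Within the same limits the largest falls were those of Penk, Nono, Fmo2, Sema6d, Sfrp4, Lrrc17, Stc1, Lman2, Gja1 and Tgfbi. Penk (chromosome 5), the enkephalin precursor, dropped from 109 ± 15.6 to 9.44 ± 2.04 CPM, a log2 fold change of -3.52 ± 0.12 (edgeR adjusted p = 5.04e-10). Fmo2, a flavin-containing monooxygenase, had a log2 fold change of -1.66 ± 0.06, the semaphorin Sema6d -1.61 ± 0.15, and Sfrp4, a secreted WNT antagonist, -1.52 ± 0.07. Lrrc17 had -1.40 ± 0.11, the secreted glycoprotein stanniocalcin 1 (Stc1) -1.26 ± 0.09, and Lman2, a lectin of the secretory pathway, -1.26 ± 0.05. Gja1 (chromosome 20), the gap junction protein connexin 43, dropped from 195 ± 2.59 to 83.6 ± 1.63 CPM (-1.22 ± 0.04), and Tgfbi, a matrix protein induced by TGF-beta, had -1.21 ± 0.13.

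Nearly all tested interferon-induced genes rose. Of 46 tested members of the interferon response list, 45 were raised and 0 lowered, both over all genes tested and adjusted over the list alone, with a median log2 fold change of 0.88 (camera adjusted p = 7.38e-40; adjusted p = 0.175 with an estimated correlation). The robust quasi-likelihood fit called 36 of them raised. Rsad2, which encodes the antiviral protein viperin, rose from 36.9 ± 14.3 to 136 ± 28.3 CPM (SD, n = 3 each), a log2 fold change of 1.89 ± 0.20 (edgeR adjusted p = 7.58e-06). Ifit3 rose by 1.88 ± 0.18, Cmpk2 by 1.71 ± 0.15, the chemokine gene Cxcl11 by 1.68 ± 0.20 and the antiviral GTPase gene Mx2 by 1.49 ± 0.21. The transcription factor gene Irf7, singled out after its values were seen, rose by 1.30 ± 0.17. The member that did not pass, Ifi27l2b, named after its values were seen, had a log2 fold change of 0.24 ± 0.14. It was raised without siCtrl replicate 1 (0.50; adjusted p = 2.10e-06), with a gene length correction (0.35; adjusted p = 0.0170) and with no filter (adjusted p = 1.31e-06). The mean log2 CPM of the list was 5.96, 5.78 and 5.34 in siCtrl replicates 1, 2 and 3 and 6.69, 6.65 and 6.65 in siNONO replicates 1, 2 and 3 (exact two-sided permutation p = 0.1), so the controls spread more than the siNONO libraries (SD 0.320 against 0.0272). Markers of macrophages and other leukocytes, genes such as Csf1r and Adgre1, did not rise with it: 0 of 16 were raised and 7 lowered, with a median of -0.14.

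**Figure D2:**
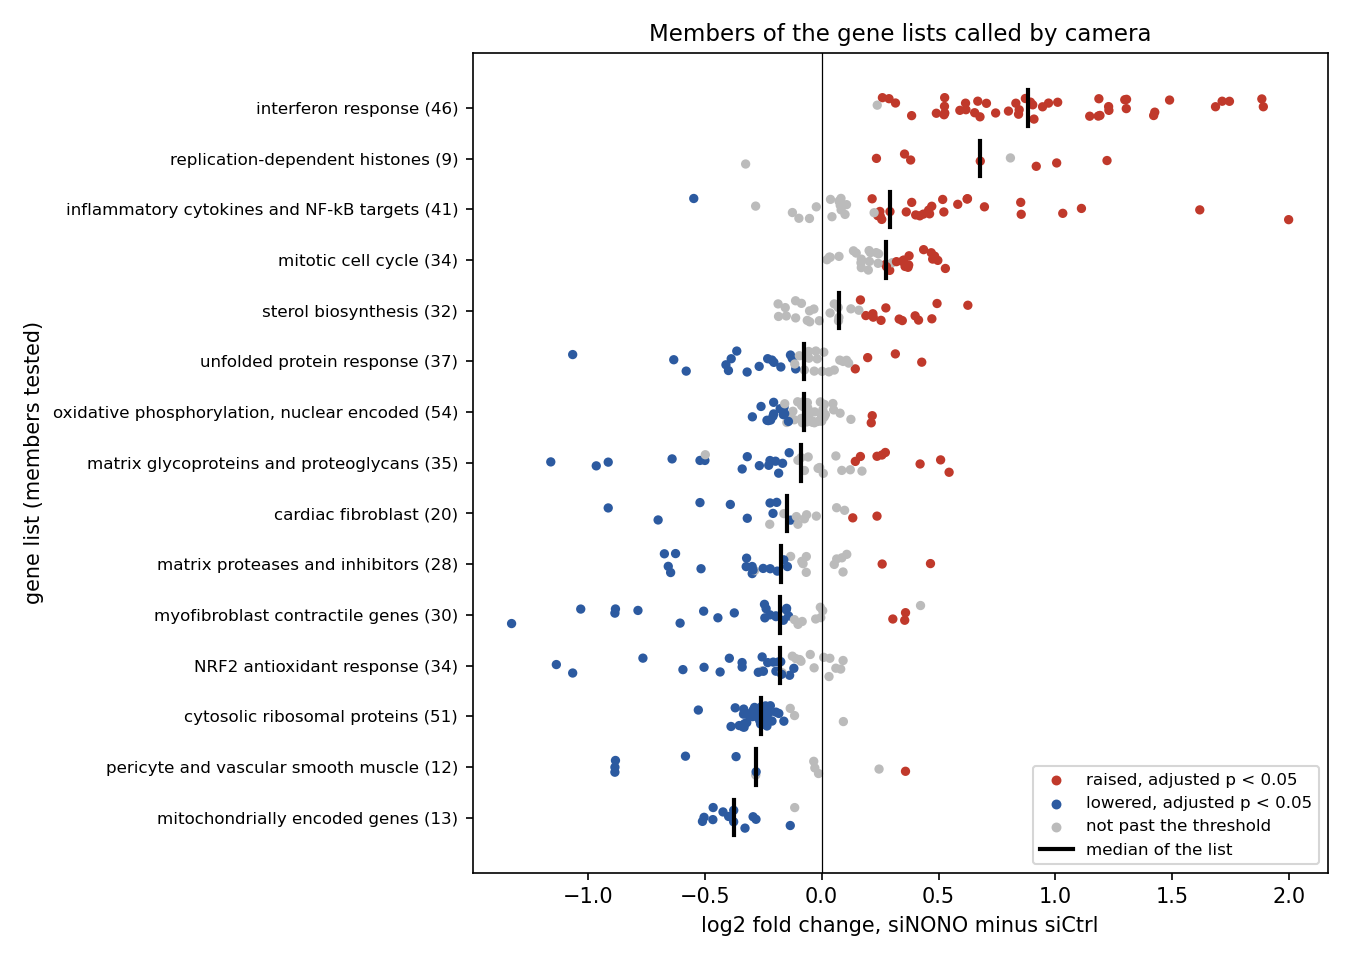
Log2 fold change (siNONO minus siCtrl, horizontal axis) of each tested member of the 15 gene lists that camera called with its preset correlation, with the number of tested members after each name; red and blue points passed edgeR's test, grey points did not, and the black bar is the list's median. The interferon response list lies farthest to the right, with a median of 0.88, and the mitochondrially encoded genes farthest to the left, with a median of -0.38.

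Inflammatory genes were more often raised than lowered. Of 41 tested members of the list of inflammatory cytokines and NF-kB targets, 26 were raised and 1 was lowered (27 and 2 adjusted over the list alone), with a median of 0.29 (camera adjusted p = 8.18e-10; adjusted p = 0.238 with an estimated correlation). Csf3, the granulocyte colony-stimulating factor, rose from 0.502 ± 0.0229 to 2.02 ± 0.0466 CPM (edgeR adjusted p = 9.88e-06), and Nos2, the inducible nitric oxide synthase, from 1.73 ± 0.621 to 5.33 ± 0.367 CPM (1.62 ± 0.18). The eosinophil chemokine Ccl11 was the lowered member, at -0.55 ± 0.13, and 2 members were lowered without siCtrl replicate 3. Il6 (0.24 ± 0.06) and complement C3 (0.70 ± 0.04), both singled out after their values were seen, rose, and Tnf, likewise singled out, did not pass (-0.28 ± 0.14) except without siCtrl replicate 3 (-0.41; adjusted p = 0.0379).

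Of the contractile genes that mark myofibroblasts more were lowered than raised, and lowered were also 6 of 12 markers of pericytes and vascular smooth muscle (median -0.28), a list that shares 2 genes with them. Of 30 tested contractile genes, 19 were lowered and 3 raised (21 and 3 adjusted over the list alone), with a median of -0.18 (camera adjusted p = 9.27e-07; adjusted p = 0.175 with an estimated correlation). With total library size or log2(FPKM + 1) 13 were lowered, and 12 with at least 1 FPKM in 3 libraries, with 3 raised in each. Acta2 (chromosome 1), the smooth muscle actin that defines myofibroblasts, dropped from 774 ± 18.0 to 379 ± 11.7 CPM (SD, n = 3 each), a log2 fold change of -1.03 ± 0.04 (edgeR adjusted p = 1.27e-09). Tagln, singled out after its values were seen, had -0.79 ± 0.05. Actg2 had -1.33 ± 0.35 at under 1 CPM, and its call ended without siCtrl replicate 3 (adjusted p = 0.0587). The raised members were the actin-binding protein gene Cald1 (0.36 ± 0.04), the integrin gene Itgb5 (0.36 ± 0.04) and, outside the naming rule, the tropomyosin gene Tpm4 (0.30 ± 0.06). Of 21 tested collagens, 5 were raised and 10 lowered (5 and 11 adjusted over the list alone; median -0.10), which camera did not call (adjusted p = 0.183), although it did without siCtrl replicate 1 (adjusted p = 0.0226) and with a gene length correction (adjusted p = 0.0255). Col8a1 (0.67 ± 0.07) and Col5a2 (0.44 ± 0.04) rose most and Col5a3 (-0.52 ± 0.05) and Col4a5 (-0.50 ± 0.06) fell most. Of the remaining raised collagens, named after their values were seen, Col8a2 had 0.26, Col18a1 0.23 and Col6a1 0.13, the last losing its call in 5 of the 6 fits without 1 library (adjusted p up to 0.156). Col1a1, Col1a2 and Col3a1, the subunits of collagens I and III and also singled out, had log2 fold changes of -0.10, 0.06 and 0.00 and did not pass. Col1a1 was lowered without siCtrl replicate 1 (adjusted p = 0.0344), with a gene length correction (0.00309), with the DESeq2 Wald test (0.0408) and with no filter (0.0249).

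Other matrix genes moved in both directions, with more of them lowered. Of 35 tested glycoproteins and proteoglycans, 8 were raised and 15 lowered (8 and 16 adjusted over the list alone), with a median of -0.09 (camera adjusted p = 0.00525; adjusted p = 0.311 with an estimated correlation). That call ended with log2(FPKM + 1) (adjusted p = 0.0516) and log2(FPKM + 0.1) (adjusted p = 0.0619). Nid1, a basement membrane linker, dropped from 889 ± 42.4 to 398 ± 13.9 CPM (-1.16 ± 0.05), Efemp1 had -0.96 ± 0.07 and Postn, singled out after its values were seen, -0.64 ± 0.05. Elastin (Eln, 0.55 ± 0.06) and tenascin C (Tnc, 0.51 ± 0.04) rose. Matrix proteases and their inhibitors were lowered in 15 of 28 and raised in 2 (17 and 2 adjusted over the list alone; median -0.18; camera adjusted p = 3.07e-05; adjusted p = 0.175 with an estimated correlation). In this list Adam12 (-0.67 ± 0.05), Adamts4 (-0.66 ± 0.08) and the protease inhibitor gene Timp3 (-0.52 ± 0.11, singled out after its values were seen) fell, and the aggrecanase gene Adamts5 (0.47 ± 0.07) rose. The other raised protease, Adamts9 (0.26 ± 0.07), lost its call without siCtrl replicate 3 (adjusted p = 0.0512) and without siNONO replicate 3 (adjusted p = 0.0994). Of 23 tested genes for collagen processing and crosslinking, 4 were raised and 6 lowered, the same counts as adjusted over the list alone. Their median (-0.03) was below 0 and their mean (0.02) above it, and camera, which pointed up, did not call the list (adjusted p = 0.889). The raised members were the crosslinking enzyme gene Lox, from 568 ± 15.1 to 1084 ± 41.4 CPM (0.93 ± 0.04), Loxl4 (0.60 ± 0.08) and, outside the naming rule, Loxl2 (0.22) and P4ha3 (0.20), while Adamts3 (-0.39 ± 0.08) and Loxl3 (-0.29 ± 0.05) fell most. TGF-beta signalling genes and targets showed 10 raised and 7 lowered of 35 (12 and 7 adjusted over the list alone), with a median of 0.04, a mean of -0.03 and no call by camera, which pointed down (adjusted p = 0.889). Their raised count was 6 without siCtrl replicate 3, 6 without siNONO replicate 1 and 5 without siNONO replicate 3. Tgfbi and the feedback inhibitor Pmepa1 (-0.42 ± 0.05) fell, and Ltbp1 (0.42 ± 0.05) rose.

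Ribosomal protein mRNAs and mitochondrially encoded mRNAs were mostly lower after knockdown. Of 51 tested cytosolic ribosomal protein genes, 48 were lowered and 0 raised (49 and 0 adjusted over the list alone), with a median of -0.26 and quartiles of -0.29 and -0.24 (camera adjusted p = 3.07e-12; adjusted p = 0.611 with an estimated correlation). Rpl37 (-0.53 ± 0.08, at a mean of 8.17 CPM against a list median of 1171 CPM) and Rpl13a (-0.39 ± 0.06) fell most. Without siCtrl replicate 1, 45 were lowered and 1 raised, with a median of -0.20. The members that did not pass, named after their values were seen, were Rpl11 (-0.12), Rpl13 (-0.13) and Rpl6 (0.09). Without siCtrl replicate 2, Rpl11 (adjusted p = 0.0395) and Rpl13 (0.0305) were lowered, as was Rpl13 without siNONO replicate 2 (0.0290), and Rpl6 was raised without siCtrl replicate 1 (0.0228) and with a gene length correction (0.00351). These genes took 6.86% ± 0.377 of all counts in siCtrl and 5.94% ± 0.195 in siNONO (SD, n = 3 each; exact two-sided permutation p = 0.1), with the highest share, 7.28%, in siCtrl replicate 1. Of the 13 mitochondrially encoded mRNAs, 12 were lowered and 0 raised (13 and 0 adjusted over the list alone), with a median of -0.38 (camera adjusted p = 8.42e-09; adjusted p = 0.175 with an estimated correlation). ND4 (-0.51 ± 0.05) and ND3 (-0.50 ± 0.05), subunits of respiratory complex I, fell most, and COX1 (-0.12 ± 0.04), singled out after its values were seen, did not pass, although it did without siCtrl replicate 1 (adjusted p = 0.0484) and without siNONO replicate 2 (0.0211). Counts of the mitochondrial ribosomal RNAs, chosen after their values were seen, went the other way: mt-Rnr1 rose by 0.73 ± 0.07 and mt-Rnr2 by 0.73 ± 0.05. Poly(A) selection does not measure rRNA levels, so whether the rRNAs themselves rose is not known. The mitochondrial mRNAs, too, were counted only as far as poly(A) selection captured them. Mitochondrial mRNAs made up 6.01% ± 0.102 of counts in siCtrl and 5.10% ± 0.144 in siNONO, and mitochondrial rRNAs 0.110% ± 0.00755 and 0.189% ± 0.0109 (exact two-sided permutation p = 0.1 for each). Nuclear-encoded subunits of oxidative phosphorylation were lowered in 14 of 54 and raised in 2, also when adjusted over the list alone (median -0.08; camera adjusted p = 0.0417; adjusted p = 0.757 with an estimated correlation). With log2(FPKM + 1), 5 were lowered and 4 raised. Camera's call ended without siCtrl replicate 1 (adjusted p = 0.468), without siNONO replicate 1 (0.0850, with 4 lowered) and without siNONO replicate 3 (0.152, with 6 lowered). It also ended with total library size (0.1004) and with a gene length correction (0.591). Fry, a separate test, did not call the list (adjusted p = 0.266). Cox8a (-0.30 ± 0.05) and Uqcr10 (-0.26 ± 0.06) fell most, and Atp5pb (0.21 ± 0.04) rose.

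**Figure D3:**
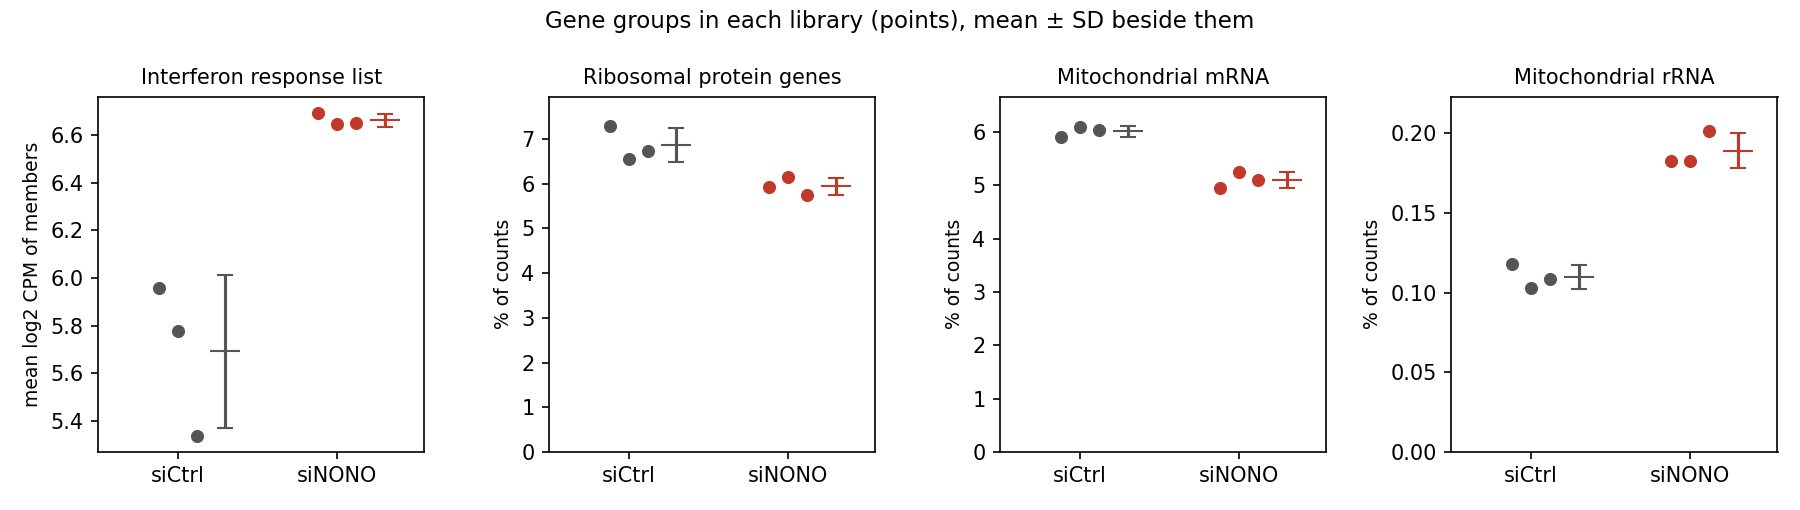
Interferon response list (mean log2 CPM of its members, log scale), cytosolic ribosomal protein genes, mitochondrial mRNAs and mitochondrial rRNAs (each in percent of all counts, linear axis from 0) in the 3 siCtrl and 3 siNONO libraries; points are libraries, and the bar beside them is the mean ± SD. In each panel the siCtrl and siNONO libraries did not overlap. Mitochondrial mRNAs lay at 6.01% and 5.10% and mitochondrial rRNAs at 0.110% and 0.189% on average, although poly(A) selection does not measure rRNA levels.

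Antioxidant genes were more often lowered and sterol synthesis genes more often raised, though many in each list did not pass. Of 34 tested NRF2 antioxidant genes, 20 were lowered and 0 raised (22 and 0 adjusted over the list alone), with a median of -0.18 (camera adjusted p = 1.08e-07; adjusted p = 0.175 with an estimated correlation). Gsta4, a glutathione transferase, dropped from 24.5 ± 1.85 to 11.2 ± 1.67 CPM (-1.13 ± 0.09), the cystine transporter gene Slc7a11 had -1.06 ± 0.12 and Nqo1, singled out after its values were seen, -0.76 ± 0.05. Without siCtrl replicate 1, 18 members were lowered and 2 raised, with a gene length correction 22 and 3, with log2(FPKM + 1) 14 and 1, and with log2(FPKM + 0.1) 13 and 1. Of 32 sterol and fatty acid synthesis genes, 13 were raised and 0 lowered (15 and 2 adjusted over the list alone), with a median of 0.07 (camera adjusted p = 0.00525; adjusted p = 0.611 with an estimated correlation). Squalene synthase (Fdft1, 0.63 ± 0.05) and the fatty acid desaturase Fads1 (0.49 ± 0.05) rose most. Lowered members appeared without siCtrl replicate 1 (2), siNONO replicate 2 (1) and siNONO replicate 3 (1). The list for the unfolded protein response had 16 of 37 members lowered and 4 raised (17 and 5 adjusted over the list alone; median -0.07; camera adjusted p = 0.00216; adjusted p = 0.175 with an estimated correlation). Slc7a11, which this list shares with the NRF2 list, and the chaperone cofactor Dnajb9 (-0.63 ± 0.05) fell most. The chaperone Hspa5 (0.32 ± 0.04) and the stress-induced transcription factor Ddit3 (0.43 ± 0.08) rose. The other raised members, Ern1 (0.20) and Calr (0.14), named after their values were seen, lost their calls in 5 and 4 of the 6 fits without 1 library (adjusted p up to 0.177 and 0.102), and the raised count was 2 without siCtrl replicate 3 and without each of siNONO replicates 1 and 2, and 8 (with 13 lowered) with total library size.

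Most tested histones and 17 of 34 mitotic genes were raised. Of 9 tested genes in the list of replication-dependent histones, 7 were raised and 0 lowered, also adjusted over the list alone. Among the 7 was H2ax, a histone variant gene that is counted again below in the double-strand break repair list. The median of the 9 was 0.68 (camera adjusted p = 9.36e-07, and 0.175 with an estimated correlation). Over the alternatives it ran from 0.37 to 0.75, with at least 5 raised. Hist1h4b rose from 7.63 ± 0.261 to 17.8 ± 0.918 CPM (1.22 ± 0.08) and Hist1h2ac by 1.01 ± 0.08 on the log2 scale, while H1f4 (-0.33) and Hist1h2bd (0.81), both under 1 CPM and named after their values were seen, did not pass. Histone genes are near-identical copies, so reads shared between them make single values uncertain. The libraries were poly(A)-selected, so these values cover polyadenylated histone transcripts only and do not measure total histone mRNA. Of 34 mitotic genes, 17 were raised and 0 lowered (19 and 0 adjusted over the list alone), at a median level of 6.64 CPM and a median of 0.28 (camera adjusted p = 4.36e-04; adjusted p = 0.620 with an estimated correlation). The kinetochore genes Ndc80 (0.53 ± 0.11) and Cenpf (0.50 ± 0.12) rose most, and the proliferation markers Mki67 (0.14 ± 0.10) and Cdk1 (0.03 ± 0.10), singled out after their values were seen, did not pass. The mitotic count was 11 without siCtrl replicate 1, 10 without siCtrl replicate 3, 11 without siNONO replicate 1 and 5 without siNONO replicate 3. DNA replication genes had 7 raised and 1 lowered of 44 (5 and 1 adjusted over the list alone), not called by camera (median 0.04; adjusted p = 0.328). Mcm10 (0.49) and Gins3 (0.48) each lost their call in 4 of the 6 fits without 1 library (adjusted p up to 0.114 and 0.187), and Tyms (-0.22 ± 0.06) was the lowered member. Of 37 double-strand break repair genes, 4 were raised and 2 lowered, also adjusted over the list alone (median 0.09; camera adjusted p = 0.376): the histone variant gene H2ax (0.35), Xrcc4 (0.33) and, outside the naming rule, Tp53bp1 (0.26) and Parp1 (0.19) rose, and Xrcc1 (-0.25) fell. Nhej1 (-0.38), the other lowered one, lost its call in 4 of the 6 fits without 1 library (adjusted p up to 0.0902). With total library size the raised counts were 11 for replication and 12 for repair, with 1 and 2 lowered.

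Among RNA-binding proteins, neither the paraspeckle list nor the splicing factor list was called by camera. Of 33 tested paraspeckle proteins, 9 were raised and 5 lowered, also adjusted over the list alone (median 0.05; camera adjusted p = 0.334). Pspc1 and Sfpq rose most, and the chromatin remodeller Smarca4 (-0.48 ± 0.04) and Hnrnph1 (-0.27 ± 0.05) fell most. The other lowered members, named after their values were seen, were Hnrnph3 (-0.24), Rbm3 (-0.16) and Rbmx (-0.16), of which Rbm3 lost its call without siNONO replicate 1 (adjusted p = 0.0588) and Rbmx in 5 of the 6 fits without 1 library (adjusted p up to 0.209). The paraspeckle counts were 7 and 3 without siNONO replicate 1 and 5 and 4 without siNONO replicate 3. Of 50 splicing factors, 13 were raised and 2 lowered, also adjusted over the list alone (median 0.04; camera adjusted p = 0.0924). Camera called this list raised without siCtrl replicate 2 (adjusted p = 0.0490). With all libraries it did so with total library size (0.0329), limma-voom (0.0403), no filter (0.0292) and the 3 FPKM fits (0.0139 to 0.0329). Fry, a separate test, also called the list raised (adjusted p = 0.0455). Raised were 8 members without siNONO replicate 1 and 7 without siNONO replicate 2. The lowered count was 4 without siCtrl replicate 1 and 1 without siCtrl replicate 3, siNONO replicate 1 or siNONO replicate 2. Hnrnpf (0.48 ± 0.04) and the SR protein gene Srsf2 (0.36 ± 0.06) rose most and Snrpd2 (-0.28 ± 0.06), a core spliceosomal protein, fell. Srsf9 (-0.14) lost its call in 4 of the 6 fits without 1 library (adjusted p up to 0.150).

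The remaining pathway lists were not called by camera and held members moving both ways. Of 33 p53 targets, 8 were raised and 13 lowered (9 and 13 adjusted over the list alone; 8 lowered without siNONO replicate 1), with a median of -0.06 (adjusted p = 0.542); the ribonucleotide reductase gene Rrm2b (0.78 ± 0.08) and Plk3 (0.51 ± 0.07) rose, and Tp53inp1 (-0.73 ± 0.04) and Pidd1 (-0.54 ± 0.09) fell. Of 40 CREB targets and immediate early genes, 10 were raised and 8 lowered (12 and 9 adjusted over the list alone; median -0.03; adjusted p = 0.590). The G protein regulator gene Rgs2 dropped from 66.4 ± 1.75 to 30.6 ± 0.548 CPM (-1.12 ± 0.05) and Gem had -0.99 ± 0.09, while Fosb rose by 0.80 ± 0.20 and Nr4a3 (0.73) lost its call in 3 of the 6 fits without 1 library (adjusted p up to 0.0832). Of 39 genes of glycolysis and hypoxia, 10 were raised and 11 lowered (11 and 13 adjusted over the list alone), with a median of 0.03, a mean of -0.02 and a downward, uncalled camera test (adjusted p = 0.590). The raised count was 5 without siNONO replicate 1 and 5 without siNONO replicate 3. Hexokinase 2 (Hk2, 0.67 ± 0.07) and Aldoc (0.36 ± 0.05) rose, and Ndrg1 (-0.67 ± 0.04) and the angiogenic factor Vegfa (-0.45 ± 0.07) fell. Of 24 circadian clock genes, 1 was raised and 3 lowered (0 and 3 adjusted over the list alone; median -0.04; adjusted p = 0.781): Dbp (-0.30 ± 0.05) fell most. Nfil3 (-0.18), named after its values were seen, lost its call without siCtrl replicate 3 (adjusted p = 0.0515) and siNONO replicate 3 (adjusted p = 0.0846), and Rora (0.20) in 4 of the 6 fits without 1 library (adjusted p up to 0.176). With total library size the balance of 3 of these lists turned, to 9 raised and 8 lowered p53 targets, 13 and 9 genes of glycolysis and hypoxia, and 6 and 2 clock genes, and with log2(FPKM + 1) to 8 and 8, 12 and 9, and 4 and 1.

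Markers of the cultured cell and of other heart cells mostly had small or negative changes. The median level was 181 CPM for cardiac fibroblast markers and 39.5 CPM for macrophage and leukocyte markers. In the other marker lists it ran from 1.43 CPM (endothelial) to 15.2 CPM (epicardial and mesothelial). Of 20 cardiac fibroblast markers, 2 were raised and 9 lowered (2 and 10 adjusted over the list alone; median -0.15; camera adjusted p = 0.00189; adjusted p = 0.175 with an estimated correlation), and 6 of the 20 also belong to other lists. Lumican (Lum, -0.91 ± 0.06) and the membrane protease Fap (-0.70 ± 0.07) fell most, Mfap5 (0.24 ± 0.05) rose and Ddr2 (0.13) lost its call in 3 of the 6 fits without 1 library (adjusted p up to 0.119). Of 12 pericyte and vascular smooth muscle markers, 1 was raised and 6 lowered (1 and 7 adjusted over the list alone; median -0.28; camera adjusted p = 0.00595; adjusted p = 0.175 with an estimated correlation). With genes of at least 1 FPKM in 3 libraries that call ended (adjusted p = 0.148) and the median was 0.02. Lmod1 (-0.88 ± 0.09) and smooth muscle myosin (Myh11, -0.88 ± 0.15) fell, and the raised marker Des (0.36) lost its call without siNONO replicate 1 (adjusted p = 0.0510) and siNONO replicate 2 (adjusted p = 0.0589). Macrophage and leukocyte markers, 0 raised and 7 lowered of 16 (0 and 8 adjusted over the list alone), were not called (camera adjusted p = 0.0552), although they were without siCtrl replicate 2 (adjusted p = 0.00399) and without siNONO replicate 2 (adjusted p = 0.0180), with the DESeq2 Wald test (0.0408), limma-voom (0.0247), no filter (0.0374) and the 3 FPKM fits (0.0268 to 0.0332); Adgre1 (-0.50 ± 0.06) and Csf1r (-0.30 ± 0.06) fell most. The counts were 1 raised and 4 lowered without siCtrl replicate 3, and 0 and 4 without siNONO replicate 3. The other marker lists were not called either. Among 6 cardiomyocyte markers, 0 were raised and 1, Tnnt2 (-0.45 ± 0.05), was lowered (median -0.30, camera adjusted p = 0.339, fry adjusted p = 0.0455). Over the alternatives their median ran from -0.37 to 0.06, with up to 1 raised. Among 9 endothelial markers, Flt1 (-0.34 ± 0.07) fell and Tek (0.24) lost its call in 5 of the 6 fits without 1 library (adjusted p up to 0.1003; median -0.02; camera adjusted p = 0.696). Among 7 epicardial and mesothelial markers, 3 were raised and 1 lowered (5 and 1 adjusted over the list alone). Their median was 0.42 (camera adjusted p = 0.667) and ran from 0.16 to 0.47 over the alternatives. Aldh1a2 (0.42 ± 0.04) and mesothelin (Msln, 0.42 ± 0.06) rose and Upk1b (-1.14 ± 0.07) fell. Wt1 (0.13), the remaining raised marker and named after its values were seen, lost its call in each of the 6 fits without 1 library (adjusted p up to 0.147). Of 6 Schwann and glial markers, 1, Ncam1 (-0.20 ± 0.04), was lowered (median -0.09; camera adjusted p = 0.590). The cardiomyocyte, endothelial and glial counts were the same adjusted over the list alone.

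Camera with its preset correlation called 5 of the 31 lists raised and 10 lowered, and 0 of them held with a correlation estimated for each list, where the lowest adjusted p was 0.175 and the lowest unadjusted p 0.0116. Fry, which asks whether a list's genes move on balance one way without comparing them with other genes, called 6 raised and 10 lowered.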

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

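The alternatives in this part were planned before the data were examined. The count of genes changed, 4630, ranged from 3369 to 4386 when 1 library was left out, and that of genes changed at least 2-fold, 266, from 250 to 310. Changed at least 2-fold were 174 genes with CPM of at least 1 in 3 libraries, 50 with log2(FPKM + 1), 145 with log2(FPKM + 0.1) and 50 with at least 1 FPKM in 3 libraries, where 1424 genes were lowered. At an adjusted p threshold of 0.01, 2852 genes changed, 1428 raised and 1424 lowered. The estimated correlation left 0 lists raised and 0 lowered. With the replicate block 3757 genes changed (1894 raised, 1863 lowered), and of 176 genes checked 11 lost and 2 gained a call, the latter Rn45s (-0.80; adjusted p = 0.00746) and Rn28s (-1.03; adjusted p = 0.00178). The correlation of deviations between siCtrl and siNONO libraries of the same replicate number, which a true block would raise, was -0.0472, -0.0862 and -0.00683. The DESeq2 Wald test changed 3915 genes, with 280 left without an adjusted p. Over all 3677 comparisons of single genes 3489 calls stayed, 146 were lost, 42 were gained and 0 reversed. The genes compared were picked by the naming rule or after their values were seen, which favours calls that stay. Of all 4630 calls, 3295 stayed without siNONO replicate 1 and 3978 without siCtrl replicate 1, the fewest and most when 1 library was left out. Over 678 comparisons of lists 633 stayed, 25 were lost and 20 gained. The robust fit left 36 interferon members raised. It ended the calls of Cxcl10 (log2 fold change 1.30, adjusted p = 0.0518) and Isg15 (1.23, adjusted p = 0.0713), both named after their values were seen.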

Other observations

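The groups in this paragraph and the next were composed after their values were seen. Their camera p-values therefore describe these data and are not a separate test of the groups. Some further immune genes were more often raised than lowered. RT1 class I genes present peptides to T cells and are near-identical, so that reads may be shared. Of 23 tested, 15 were raised and 0 lowered, with a median log2 fold change of 0.37 (camera adjusted p = 1.63e-05, and 0.522 with an estimated correlation). The robust quasi-likelihood fit ended the calls of RT1-S3 (0.62, adjusted p = 0.091) and RT1-T24-4 (0.72, adjusted p = 0.072). Immunoproteasome and peptide loading genes were raised in 11 of 14 and lowered in 1 (median 0.30; camera adjusted p = 1.63e-05; adjusted p = 0.522 with an estimated correlation), and 3 of them also stand in the interferon list. Among them Nlrc5, the activator of class I genes, rose by 0.88 ± 0.10 (SE) and B2m, the light chain of class I, by 0.38 ± 0.09, while Psme2 was lowered at -0.20 ± 0.07. Of 19 complement genes, 8 were raised and 2 lowered (median 0.12; camera adjusted p = 0.00509; adjusted p = 0.522 with an estimated correlation): Cfb rose by 1.70 ± 0.11 and C4b by 1.14 ± 0.09, and C6 (-1.03 ± 0.05) and C7 (-0.60 ± 0.06) fell. Constitutive proteasome subunits were raised in 13 of 31 and lowered in 1, Psmb5 at -0.15 (median 0.09; camera adjusted p = 0.00220; adjusted p = 0.549 with an estimated correlation).

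Flavin monooxygenases and glutathione transferases, enzymes that handle foreign compounds, were lowered in 13 of 19 and raised in 0 (median -0.47; camera adjusted p = 2.25e-14; adjusted p = 0.190 with an estimated correlation). Of these Gsta4, Gstp1, Mgst1 and Gstm1 also stand in the NRF2 antioxidant list, so this result is not fully separate from that one. Beside Fmo2, Fmo1 (-0.86 ± 0.09) fell. Lysosomal genes were lowered in 17 of 45 and raised in 5 (median -0.09; camera adjusted p = 0.0190; adjusted p = 0.522 with an estimated correlation), with the proton pump subunit Atp6v1a at -0.81 ± 0.04 and the protease Lgmn raised by 1.25 ± 0.06. Genes of prostaglandin synthesis and handling moved both ways, 5 raised and 7 lowered of 18, and camera did not call them (adjusted p = 0.278). The prostaglandin E synthase Ptges rose by 1.39 ± 0.06 and the transporter Slco2a1 by 1.31 ± 0.06, and Ptgs1 had -0.76 ± 0.06. Secreted WNT and BMP antagonists (5 raised and 7 lowered of 14; camera adjusted p = 0.138) and mitochondrial ribosomal proteins (5 raised and 13 lowered of 48; camera adjusted p = 0.182) were not called either. Among rRNA genes, whose levels poly(A) selection does not measure, 2 of 7 tested were raised (both mitochondrial) and 2 lowered. Rn45s (-0.61 ± 0.31) and Rn28s (-0.85 ± 0.35) did not pass. Both were lowered without siNONO replicate 3, Rn45s at -1.21 (adjusted p = 0.00148) and Rn28s at -1.50 (adjusted p = 0.00235), and with no filter.

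The regrouping of the 6 libraries, the gene length correction and the fits without 1 library were planned, while their use on the 3 patterns below, the leukocyte markers, the count of other groups, the matched random lists and the mitochondrial rRNAs were tests chosen after the result was seen. The grouping of the libraries was examined over all 10 ways to split them 3 against 3, where the share of splits as large as the real one can never be below 0.05. The real split had 4630 genes changed, 2338 raised, 2292 lowered and 266 changed at least 2-fold. By edgeR's test each of the other 9 had 0 (113 to 548 genes at an unadjusted p under 0.05), so 1 split of 10 was as large for each. However, every other split mixed siCtrl with siNONO libraries in each of its groups. Any difference between siCtrl and siNONO then adds to the spread within groups and lowers the number of calls. The 0 therefore cannot tell whether the grouping arose by chance, and no conclusion is drawn from it. Camera with its preset correlation called lists in every other split as well, between 3 and 8 in the direction with more calls. Only that larger direction was taken from the other splits. For lists raised, its smaller direction, the real split had 5 against at most 8, with 9 splits of 10 as large. That comparison sets unlike measures side by side, so no conclusion is drawn from it. For lists lowered, its larger direction, the real split had 10 against at most 8, with 1 split as large.

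The rise of the interferon response list was weighed against more leukocytes in the siNONO cultures, a single library, and siRNA delivery rather than loss of Nono. Leukocyte markers had a median log2 fold change of -0.14 (95% bootstrap interval over members -0.22 to -0.02). That interval resamples genes and does not cover the spread between libraries. Over the alternatives the median ran from -0.18 to -0.09. Abundant markers, named after their values were seen, such as Lyz2 (961 CPM, -0.12) and Cd68 (140 CPM, -0.04) did not show the rise that more leukocytes would require. Each library pools the cells of its culture, so which cells carried the interferon rise is not known. Leaving out any single library left at least 42 of 46 members raised. Whether siRNA delivery rather than loss of Nono caused the rise stays open, since there were 0 groups besides siCtrl and siNONO and the labels disagree on what the controls received. A hypothesis is that loss of Nono itself raises these genes, and a second siRNA or a rescue with siRNA-resistant Nono could test it.

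The fall of the ribosomal protein list was weighed against a gene length trend and against a shift of short and abundant transcripts in general. Its median went from -0.26 (95% bootstrap interval over members -0.27 to -0.25) to -0.20 (-0.22 to -0.16) with the gene length correction. These intervals resample genes, whose estimated correlation was 0.91, and do not cover the spread between libraries. Without siCtrl replicate 1 the uncorrected median was -0.20. With the correction 47 of 51 members were still lowered, so a length trend did not account for all of the fall. Whether it belongs to short and abundant transcripts in general stays open: 0% of 10000 random lists drawn from the nearest genes had a median as low, but those genes were longer (median length 962 against 791) and less abundant (704 against 1171 CPM), and the median of the lists was itself -0.10. Log2 fold change followed gene length with a Spearman rho of 0.11 over 14150 genes, and the other splits reached up to 0.302. No biological explanation was tested.

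The fall of mitochondrial mRNAs was weighed against less mitochondrial RNA of every kind and against a gene length trend, and the pattern was restated once, from mRNAs lowered with rRNAs raised to mRNAs lowered, after its first test. With the gene length correction the median of the mRNAs went from -0.38 (95% bootstrap interval over members -0.46 to -0.29) to -0.32 (-0.37 to -0.23). These intervals resample genes and do not cover the spread between libraries. With the correction 12 of 13 were lowered, so a gene length trend did not account for all of the fall. Less mitochondrial RNA of every kind stays open: the lower of the 2 mitochondrial rRNA log2 fold changes was 0.73, but poly(A) selection does not measure rRNA levels and this rise had been seen before it was used as a test. No biological explanation was tested.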
